A study of Rattus norvegicus with 8 samples.

How the data were processed

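RNA from left ventricular myocardium of male rats aged 2 months was measured on 8 whole-transcript expression arrays, 1 per animal. The samples fall into 2 groups of 4 by the strain in the labels. SHR is the spontaneously hypertensive rat, and PD5 is a congenic strain that carries a small foreign chromosome segment on the SHR background. The labels give no litter, batch or scan date. Animal numbers were 207, 209, 210 and 212 in PD5 and 213, 215, 218 and 219 in SHR. The strains share no number, so no pairing was used, and order by number and strain cannot be told apart. The labels' protocols state that the RNA passed a minimum integrity score.

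The deposited values were on a log2 scale, with 220231 probe sets and 1 column per array, and were processed by the authors with Partek 6.6, per the submitters' processing notes. The background correction, the normalization and the summary method are not given in the sources used here. Medians of the arrays ranged from 6.93 to 6.98, so the deposited log2 values were already on a shared scale, and they were used as deposited. The platform annotation listed 168188 of the probe sets. Of all probe sets, 166557 named 1 gene, 1631 named several and 52043 named none. Gene symbols were updated through the gene table of the GRCr8 assembly: 14377 symbols were current, 2837 were replaced through a synonym and 95 found no match. That table served only for names and for neighbourhood, because the build behind the array annotation is not given in the sources used here.

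A gene value was the mean of all probe sets that name that gene alone. This gave 17309 genes, with a median of 8 probe sets per gene and 2377 genes resting on 1 probe set. Genes were tested for PD5 minus SHR with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05 on the adjusted p. Intervals are 95% intervals of that fit unless stated otherwise. No filter on dim genes was applied. The number of arrays limits the precision.

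Before the data were examined, 26 gene lists were fixed, each tested with limma's camera at a preset correlation between genes of 0.01 and adjusted over the lists. They cover candidates around Zbtb16, hypertrophy and the fetal programme, extracellular matrix, fatty acid use, glucose use and insulin signalling, the respiratory chain, vasoactive signalling, glucocorticoid-responsive genes, genes reported as linked to PLZF, the cell cycle, the circadian clock, immediate early genes with heat shock genes, the interferon response, and markers of 13 kinds of cell or tissue. Camera was repeated with an estimated correlation, and fry was run on the same lists, for a shift in one direction and for change in either direction. The mean of each list's genes was also compared between the strains with a two-sided exact permutation test, whose smallest possible p is 0.0286. These permutation p-values were not adjusted over the lists. Members of each list were counted past the threshold over all genes and adjusted over the list alone.

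The genes named in the text follow a rule also fixed before the data were examined. It takes the measured candidates around Zbtb16, up to 12 genes per direction that passed with groups that do not overlap, and the next genes by unadjusted p up to 12, given as values. It adds up to 4 members of each list that was called or held a passing member, and 1 member of every other list. Symbols of unnamed loci and of receptor or RNA families were left out of the first of these parts. Genes named outside the rule are marked as chosen after their values were seen. Probe sets were also tested singly, and genes with at least 3 probe sets were tested with limma's diffSplice for probe sets that move apart. A Fisher exact test compared genes within 1 Mb of Zbtb16 with the rest. The extent of the PD5 segment is not given in the sources used here: the candidates come from general knowledge, and the window was chosen, so neither stands for the whole segment.

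The functions were tested on simulated data with the means and spreads of these 17309 genes. Among 200 changed genes, 60% of those shifted by a log2 change of 0.5 were recovered, 96% of those shifted by 1, 96% of those shifted by 1.5 and 100% of those shifted by 2, while 13 unchanged genes were called. That simulation called 189 genes and the real comparison 9, so the same adjusted threshold asked for a smaller unadjusted p there. Recovery of real changes of these sizes can therefore be lower than these shares. In a simulation with no change, 0 genes and 0 lists were called. Its genes were drawn independently of each other. It therefore cannot tell how often camera calls lists falsely where genes move together. For diffSplice, which assumes 1 spread for all probe sets of a gene, a simulation with no change called 0 of 14283 genes under that assumption. It called 176 genes when each probe set kept the spread it has in these data, so its count of real calls has no firm meaning here.

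Alternatives were another quantile normalization, median centring, removal of the dimmest genes or probe sets, the median or the brightest probe set per gene, a trended robust variance model, array weights, an ordinary test without moderation, tests of single probe sets, other thresholds and windows, and each array left out in turn. After seeing the data, the joint removal of PD5 210 and SHR 219, the arrays with the lowest mean correlation with the rest, was added. A gene or list that passed under neither of the settings compared was counted as unchanged even where its sign differed. Figures were drawn with matplotlib.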

Results

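Gene expression in the left ventricle was compared between 4 PD5 and 4 SHR males at 2 months of age, to ask what a small congenic segment changes in the heart of a hypertensive rat. Array values correlated at a mean r of 0.958 across probe sets both within and between the strains, so this measure did not separate them. It does not tell how many genes differ. The lowest mean correlations with the other arrays were 0.950 in SHR 219 and 0.952 in PD5 210.

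The nuclear receptor genes Nr4a1 and Nr4a3, which are switched on within minutes to hours of a stimulus, were the genes with the largest rise in PD5. Nr4a1 rose by 2.04 on the log2 scale (SE 0.17), from 7.22 ± 0.24 in SHR to 9.26 ± 0.31 in PD5 (SD, n = 4 each), a 4.11-fold difference with an adjusted p of 0.00849 in limma. Nr4a3 rose by 1.87 (SE 0.20, adjusted p = 0.0224). Irs2, an adaptor of the insulin receptor, rose by 0.94 (SE 0.12, adjusted p = 0.0404). Kcna5, a voltage-gated potassium channel gene, fell by 1.47 (SE 0.14, adjusted p = 0.0117), from 8.38 ± 0.28 in SHR to 6.91 ± 0.16 in PD5.

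The other genes that fell were Timp4, an inhibitor of matrix metalloproteinases, by 1.06 (SE 0.13, adjusted p = 0.0404), Ddit4, an inhibitor of mTOR signalling, by 1.03 (SE 0.13, adjusted p = 0.0404), Nfkbia, which encodes an inhibitor of NF-κB, by 0.91 (SE 0.08, adjusted p = 0.0117), and Ch25h, a cholesterol hydroxylase, by 0.89 (SE 0.10, adjusted p = 0.0249). Cryge, a lens crystallin gene, also passed (adjusted p = 0.0444), but its single probe set lay at 2.74 in PD5 and 2.17 in SHR, at the 1.3 percentile of gene levels and too low to give the size of the difference. Kcna5 and Ch25h also rest on 1 probe set each. In all, 9 of 17309 genes passed, 4 higher and 5 lower in PD5, Cryge among them, and in each the 4 PD5 animals lay on one side of the 4 SHR animals. At an unadjusted p under 0.05 there were 983 genes, where chance gives 865, and the groups did not overlap in 3.49% of genes, where chance gives 2.86%. The count of 9 fell to between 1 and 7 when any one array was left out, and to 0 without both PD5 210 and SHR 219. It was also 0 in an ordinary test without moderation and with the brightest probe set per gene. It rose to 25 with the dimmest genes left out, 8 higher and 17 lower, and to 47 with a trended robust variance model, 15 higher and 32 lower, so the balance of directions depends on the method.

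**Figure D1:**
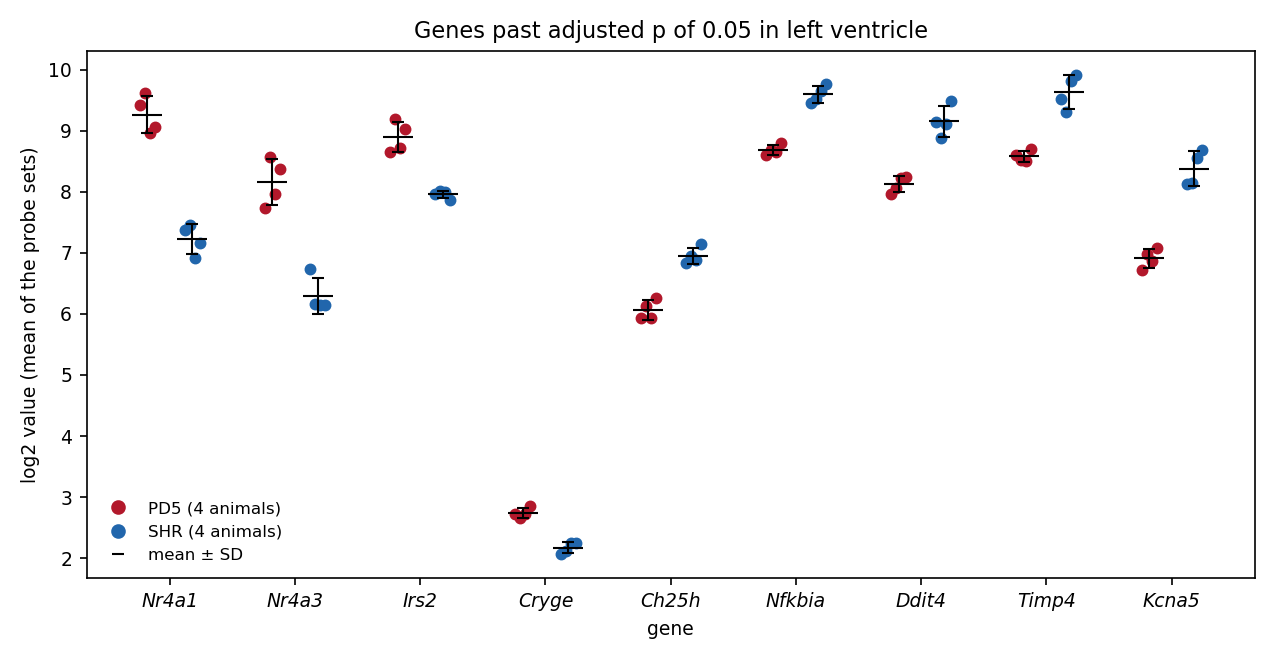
Log2 value (y axis) of the 9 genes that passed, in each of 4 PD5 and 4 SHR animals, with bars at the mean ± SD. In each gene the PD5 and SHR points do not overlap, and Nr4a1 shows the widest gap, 2.04 on the log2 scale.

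Several genes came close without passing. Nr4a2, the remaining member of the Nr4a family, was higher in PD5 by 1.34 (SE 0.18, adjusted p = 0.0531), and Has2, a hyaluronan synthase gene, by 0.55 (SE 0.07, adjusted p = 0.0511). Next on the higher side were Ptger4 at 0.46, Nrarp at 0.47, Ect2 at 0.46, Slitrk6 at 0.60, Mycn at 0.59 and Rgs2 at 0.39, with adjusted p from 0.105 for Ptger4 to 0.218 for Rgs2. On the lower side, log2 differences were -0.69 for the chemokine receptor Ccr1, -0.55 for Bcl2l1, -0.40 for the adenosine receptor Adora2a, -0.51 for Klf9, -0.40 for Lyve1, -0.70 for the clock gene Per1 and -0.79 for Adamts15, with adjusted p from 0.105 for Ccr1 to 0.128 for Adamts15.

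Genes that respond to glucocorticoid hormones were lower in PD5. Of 23 measured members 17 were lower, 2 fell over all genes (Nfkbia and Ddit4), and 11 fell when adjusted over the list alone, with a median log2 difference of -0.29. Among these 11 were Sult1a1, a sulfotransferase, at -1.04 (SE 0.24), Fkbp5, a chaperone of the glucocorticoid receptor, at -0.77 (SE 0.25, and -0.49 without SHR 219), Pdk4 at -0.64 (SE 0.12) and Klf9 at -0.51 (SE 0.08). None of these 4 passed over all genes. The camera adjusted p was 3.16e-15, and the adjusted p was 0.194 with an estimated correlation. The mean of the list was the most extreme of all arrangements of the 8 animals (exact permutation p = 0.0286, the smallest possible and not adjusted over the lists). The fatty acid list, which camera did not call, had the same permutation p. In fry the adjusted p of the glucocorticoid list for a shift in one direction was 0.0329, the only list to pass there.

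Immediate early genes were higher in PD5. In the list that joins them with heat shock genes, 13 of 19 members were higher, 2 rose over all genes (Nr4a1 and Nr4a3), and 7 rose when adjusted over the list alone. Those 7 included the transcription factor genes Fos, at 1.65 (SE 0.33), and Egr1, at 1.07 (SE 0.36), neither of which passed over all genes. The median difference was 0.18, or 0.09 without SHR 218, and the camera adjusted p 1.53e-06, with an adjusted p of 0.194 with an estimated correlation. The exact permutation p of the list mean was 0.0286. The heat shock members did not share the direction: all 5 had log2 differences below 0, with a mean of -0.10 and an interval from -0.29 to 0.09.

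**Figure D2:**
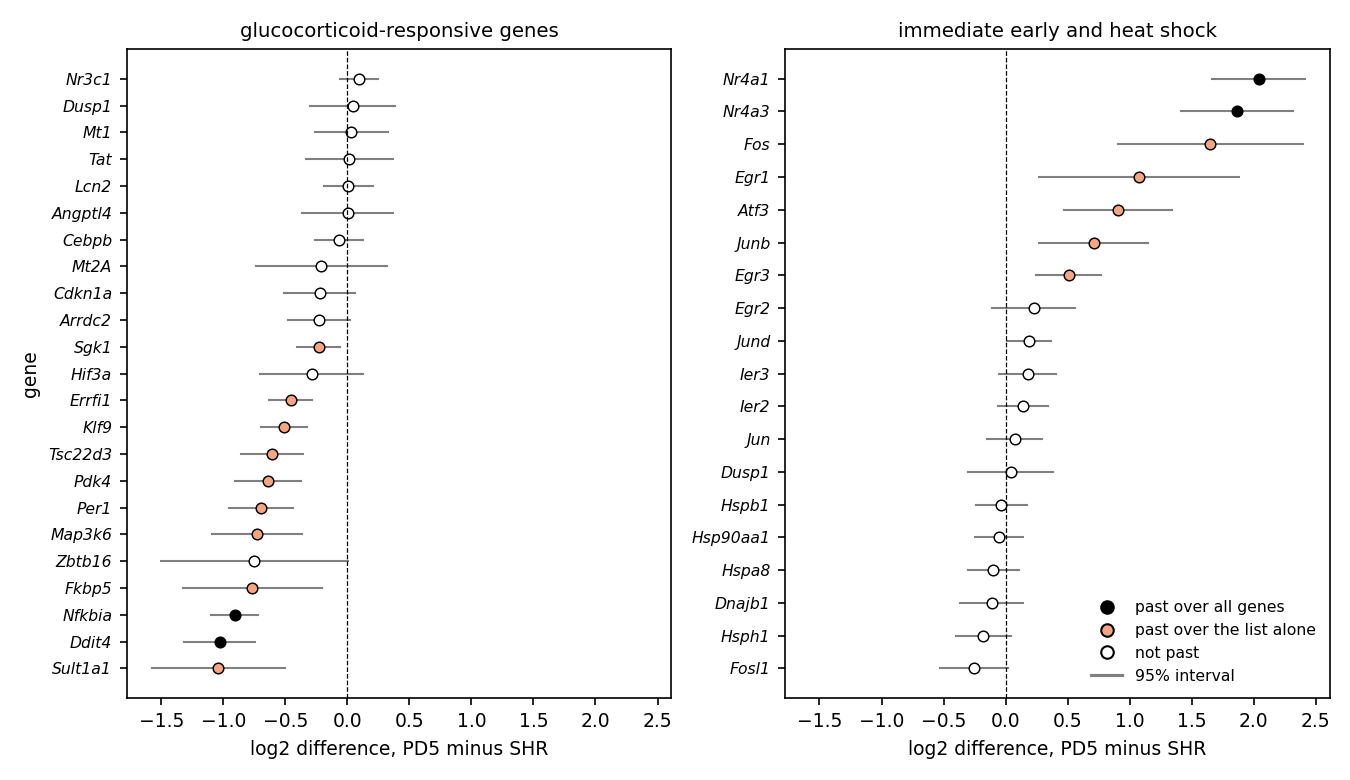
Log2 difference, PD5 minus SHR (x axis), of each measured member of the glucocorticoid-responsive list (left, 23 genes) and of the immediate early and heat shock list (right, 19 genes), with 95% intervals as lines. Filled points passed over all genes and light points over the list alone, and 17 members on the left lie below 0.

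Smaller shifts were called in 3 further lists. Respiratory chain genes were slightly lower in PD5, with 31 of 41 members below 0, a median of -0.04 and a camera adjusted p of 0.0138. The adjusted p was 0.744 with an estimated correlation. The exact permutation p of the list mean was 0.0571. None of these genes passed over all genes or adjusted over the list alone, and the largest difference was in Ndufa1, at -0.43 (SE 0.16), followed by Ndufa2 at -0.21 (-0.32 without PD5 210 and -0.12 without SHR 215), Ndufa8 at -0.14 and Uqcrq at -0.10. Markers of thymus and mesothelium, the tissues that can adhere to a dissected heart, were lower in 10 of 11 genes, with a median of -0.19, a camera adjusted p of 0.0167, an adjusted p of 0.194 with an estimated correlation and an exact permutation p of 0.0286. The mesothelial genes Upk3b at -0.59, Msln at -0.34 and Krt19 at -0.31 led that list, with the thymic gene Dntt at -0.24, and 0 members passed over all genes or adjusted over the list alone. Without SHR 219 these were -0.37 for Upk3b, -0.08 for Msln and -0.12 for Dntt, while Msln was at -0.54 without SHR 218 and Dntt at -0.36 without SHR 215. This shift ran in the same direction as that of the glucocorticoid-responsive list. Interferon response genes were higher in 22 of 27 members, with a median of 0.07, a camera adjusted p of 0.0496, an adjusted p of 0.970 with an estimated correlation and an exact permutation p of 0.600. Its leading members were Isg15 at 0.41, Rsad2 at 0.26, Gbp5 at 0.20 and Irf1 at 0.20 (Isg15 at 0.27 and Gbp5 at 0.10 without SHR 218), and 0 passed over all genes or adjusted over the list alone. The interferon call ended without PD5 207 (median -0.030, adjusted p = 0.714), SHR 213 (adjusted p = 0.343) or SHR 218 (adjusted p = 0.436), with median centring (adjusted p = 0.0517) and with the brightest probe set (0.203). The respiratory chain call ended without PD5 209 (adjusted p = 0.0549), PD5 210 (0.0890), SHR 213 (0.0561) or SHR 218 (0.242) and with the brightest probe set (0.203), and the thymus and mesothelium call without PD5 210 (median -0.13, 0.0890) or SHR 218 (0.0560). Over 17 settings, the first included, camera called the respiratory chain list in 11 and the thymus and mesothelium list in 13. The thymus and mesothelium median was -0.10 without SHR 215 and -0.11 without SHR 219, and with the brightest probe set it was -0.05 and not called (adjusted p = 0.434). The interferon median was 0.12 without PD5 210 and 0.02 without SHR 218.

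Cardiac programmes linked to hypertension were not called by camera. Hypertrophy and fetal genes had a median of -0.01 over 21 members (adjusted p = 0.913), with Myh7, the slow myosin heavy chain, at 0.29 (SE 0.15, and 0.14 without PD5 207). Extracellular matrix genes had a median of -0.03 over 35 members (adjusted p = 0.610), with Col8a1 at -0.35 (SE 0.12). In vasoactive signalling the median was 0.02 over 28 members (adjusted p = 0.847). There Rgs2 rose when adjusted over the list alone, and Edn1, the endothelin precursor gene, was at -0.39 (SE 0.12). No member of these 3 lists passed over all genes. In fry, tested for change in either direction, vasoactive signalling was called (adjusted p = 0.0343) and the other 2 were not.

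Among metabolic lists, fatty acid use had a median of -0.03 over 34 members (adjusted p = 0.0701), where 0 genes passed over all genes and Pdk4 fell when adjusted over the list alone. Glucose use and insulin signalling had a median of -0.01 and a mean of 0.03 over 32 members (adjusted p = 0.913), where Irs2 rose both over all genes and adjusted over the list alone. Its members Pfkfb2 at 0.37, Pik3r1 at -0.33 and Pfkfb1 at -0.18 did not pass. Genes reported as linked to PLZF, the protein encoded by Zbtb16, had a median of 0.01 and a mean of -0.06 over 17 members (adjusted p = 0.913). Ddit4 fell there over all genes and adjusted over the list alone, while Dusp6 was at -0.26 and Igf2 at 0.18. Cell cycle genes had a median of 0.06 over 22 members (adjusted p = 0.0901), with Mcm5 at 0.23. Left-out arrays moved calls in 2 of these lists. The cell cycle list was called without PD5 207 (median 0.13, adjusted p = 9.54e-05), PD5 212 (0.07, 0.0490), SHR 215 (0.09, 0.0302) or SHR 219 (0.07, 0.0495), while without PD5 210 its median was -0.0044 (adjusted p = 0.925). The fatty acid list was called without PD5 207 (adjusted p = 0.0234) or SHR 219 (0.0126), while its median was -0.016 without PD5 210 and -0.0035 without SHR 213 (adjusted p = 0.534). In the circadian clock the median was -0.06 over 17 members (adjusted p = 0.610), where Per1 fell when adjusted over the list alone and 0 genes passed over all genes. Fry in either direction called the lists of glucose use (adjusted p = 0.000347), PLZF (0.000347) and the clock (0.0334), whose members lay on both sides of 0. Irs2, Ddit4 and Per1 were the only members of these lists, in that order, to pass adjusted over the list alone. Ddit4 and Per1, like Pdk4 of the fatty acid list, also belong to the glucocorticoid-responsive list, so these results are not separate from it.

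Among the remaining marker lists, camera called no cell type, and in limma 0 members passed over all genes or adjusted over the list alone. Medians were 0.00 for cardiomyocytes (adjusted p = 0.996, Myom1 at 0.07), 0.01 for fibroblasts (adjusted p = 0.913, Mfap5 at -0.20) and 0.03 for endothelium (adjusted p = 0.913, Fabp4 at -0.22). Endothelial markers were called by fry in either direction (adjusted p = 7.97e-08), with 6 of 10 higher and 4 lower. Smooth muscle and pericytes had a median of 0.00 (adjusted p = 0.847, Pdgfrb at 0.09) and macrophages and monocytes of -0.07 (adjusted p = 0.277, Cd163 at -0.41). Lymphocyte markers had a median of -0.04 (adjusted p = 0.913, Ms4a1 at 0.20), granulocyte and mast cell markers of -0.02 (adjusted p = 0.913, Cxcr2 at -0.34 and at -0.15 without SHR 219) and erythroid markers of 0.05 (adjusted p = 0.847, Slc4a1 at 0.12). Atrial markers had a median of 0.17 (adjusted p = 0.128), with Myl7 at 0.62 (SE 0.55), and were called without SHR 219 (median 0.23, adjusted p = 0.00734, Myl7 at 1.18). Without SHR 215 the median was 0.05 (adjusted p = 0.527) and Myl7 at 0.12. Adipocyte markers had a median of 0.22 (adjusted p = 0.610), with Ucp1 at 1.20 (SE 0.97), and both rest on PD5 210, without which the median was -0.07 and Ucp1 at 0.029. Schwann cell and neuron markers had a median of 0.10 (adjusted p = 0.667, Uchl1 at -0.22; called with the median of the probe sets, adjusted p = 0.00378) and skeletal muscle markers of 0.03 (adjusted p = 0.498, Pvalb at 0.31).

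The extent of the PD5 segment is not given in the sources used here, so the candidates below are genes around Zbtb16 taken from general knowledge, and the window of 1 Mb was a choice. Zbtb16, which encodes the transcription factor PLZF, was at 7.74 ± 0.04 in PD5 and 8.49 ± 0.81 in SHR (SD, n = 4 each), a log2 difference of -0.75 (SE 0.33, 95% interval -1.50 to 0.00), which did not pass (adjusted p = 0.873). The wide SHR spread came from the animals: SHR 218 and SHR 219 were at 8.85 and 9.47, and SHR 213 and SHR 215 at 7.91 and 7.74. Without SHR 219 the difference was -0.42, the smallest with one array left out. The other 12 candidates near it lay within 0.19 of 0, with Nnmt at 0.19, Ttc12 at -0.15, Ankk1 at 0.14, Ncam1 at 0.14, Htr3a at -0.12, Tmprss5 at 0.11, Drd2 at 0.11, Rbm7 at 0.08, Rexo2 at -0.06, Zw10 at -0.05, Htr3b at 0.01 and Usp28 at 0.01. Of the 13 measured candidates, 0 passed over all genes and 0 adjusted over the list alone, where the smallest adjusted p was 0.595, and 0 had an unadjusted p under 0.05 in limma. The list's camera adjusted p was 0.913. In the wider set of 16 genes within 1 Mb, Nxpe1 was lower in PD5 by a log2 difference of -0.26 (SE 0.06), which passed adjusted over those 16 genes (adjusted p = 0.0291) and not over all genes (adjusted p = 0.414). It was named after its value was seen.

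**Figure D3:**
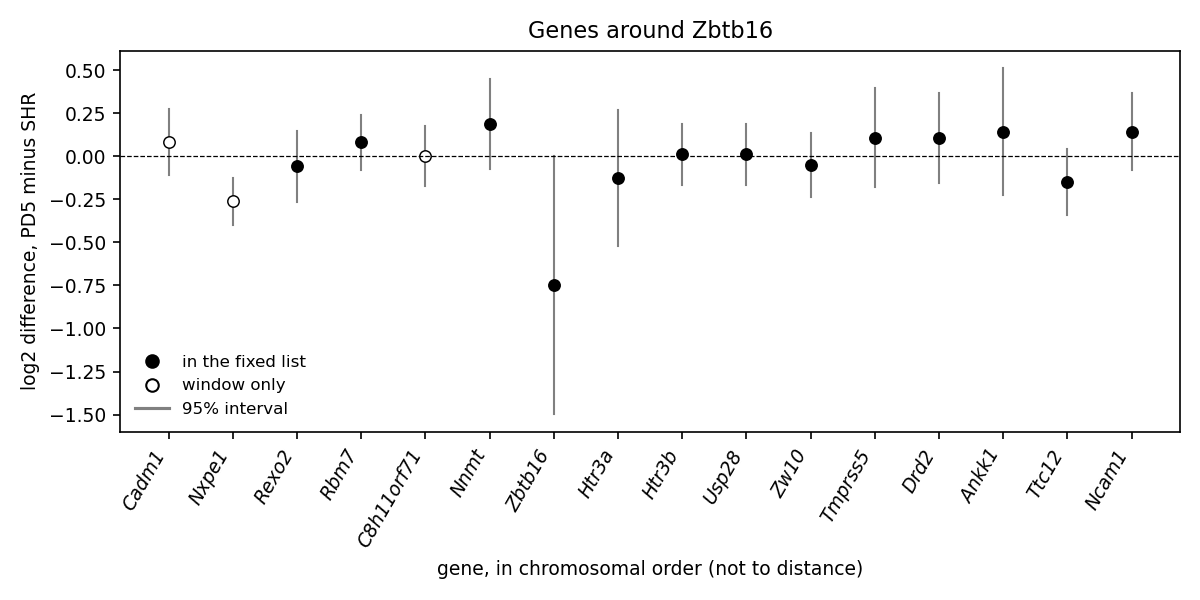
Log2 difference, PD5 minus SHR (y axis), of the 16 tested genes within 1 Mb of Zbtb16, in the chromosomal order of the GRCr8 assembly (x axis, not drawn to distance), with 95% intervals as lines. Zbtb16 has the widest interval, from -1.50 to 0.00, and Nxpe1 lies below 0 with its whole interval.

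Of the 9 genes that passed, 0 were among the 16 tested genes within 1 Mb of Zbtb16. With so few genes on either side, a Fisher exact p of 1 follows from any count of 0, so it does not tell whether they avoid the segment, whose extent is not given in the sources used here. They lay on 8 chromosomes other than that of Zbtb16, with Kcna5 and Timp4 both on chromosome 4.

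Of single probe sets, 2 of 220231 passed over all probe sets. They were a probe set of Nr4a3, higher in PD5 by 2.71 (SE 0.16), and one of Epha7, an ephrin receptor gene, at 5.16 in PD5 and 2.18 in SHR, both with an adjusted p of 0.0254. Among the 53674 probe sets with no single gene, 0 passed in limma, and 2788 had an unadjusted p under 0.05. Of the 176 probe sets of genes within 1 Mb of Zbtb16, a window that may be wider or narrower than the segment, 1 passed adjusted over those probe sets alone. This was a Cadm1 probe set at 5.45 in PD5 and 3.97 in SHR (adjusted p = 0.0280), with an adjusted p of 0.524 over all probe sets. The SHR levels of the Epha7 and Cadm1 probe sets are too low to give the size of their differences. Epha7 and Cadm1 were named after their values were seen.

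Probe sets of the same gene moved apart in 61 of 14283 genes by limma's diffSplice, and in 0 of the genes around Zbtb16. The count cannot be read as exon-level change, because the same test called 176 genes in simulated data with no change when each probe set kept its own spread. It was 132 without SHR 218 and 8 without PD5 212.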

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

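Tests of the time of day, of the order of collection, of single arrays, of handling and heat shock, of Zbtb16 and of fry over other splits were chosen after the results were seen, while the second glucocorticoid list, the list of other activity-dependent genes and the other counts over splits were written down before their values were seen.

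The counts were repeated over the 35 ways to split the 8 arrays into 2 groups of 4. The strain split gave 9 genes and was the only 1 to reach that count, with 0 as the highest of the others. A share of 1 in 35 is the smallest this check can give, so chance is less likely for the gene count but not excluded. For single probe sets the real count was 2, again reached by 1 split, with 1 as the highest of the others. For gene lists called by camera chance cannot be excluded: 10 splits called at least 5 lists, and the highest of the others called 7. In fry in either direction 7 lists were called, a count reached by 1 split alone, with 1 as the highest of the others. This is again the smallest share possible, so chance is not excluded for that count either. The 61 genes whose probe sets moved apart were matched or exceeded by 6 splits, the real one included, and the split of PD5 207, PD5 209, PD5 212 and SHR 218 against the rest gave 596. Because that test also calls genes in simulated data with no change, whether a structure of the samples lies behind this count was left open.

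The glucocorticoid-responsive genes, lower in PD5, may reflect a lower glucocorticoid signal in these hearts at collection. A second list of hormone-induced genes, with none of the first list's members, had a median log2 difference of -0.11, with 15 of 18 genes lower, a camera p of 2.26e-05 and a p of 0.00700 with an estimated correlation. No single array accounts for the direction, since the first list's median ranged from -0.43 to -0.23 with one array left out. Its highest adjusted camera p was then 6.16e-11 at the preset correlation. This check was not repeated with an estimated correlation. A different time of day stays open. Clock genes high towards lights on minus those high towards lights off, without Per1 and Per2, differed by 0.26, PD5 minus SHR. That is the direction that collection of PD5 nearer to lights on would give, and it did not pass (exact permutation p = 0.0571). Of the genes high towards lights on, 4 of 4 were higher in PD5, and of the others 5 of 6 were lower. Whether the animal numbers follow the order of collection is not given in the sources used here. Order by number cannot be told apart from strain, because 0 SHR animals were numbered below the highest PD5 animal. A difference in handling therefore remains as open as an effect of the segment.

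The immediate early genes, higher in PD5, may belong to a wider activity-dependent response. Other cAMP- and activity-dependent genes had a median difference of 0.14, with 9 of 12 higher and a camera p of 0.000649, and a p of 0.0827 with an estimated correlation. A heat shock response is argued against by the heat shock genes, whose mean difference was -0.10, although the upper bound of 0.09 lay close to the limit of 0.1 set for it. A fast response to handling could not be separated: the fast responders other than the Nr4a genes differed by a mean of 0.55, but all 10 of them belong to the list that showed the pattern, which makes that comparison void. The strain itself stays among the open explanations and was not tested apart from collection.

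Zbtb16, lower in PD5 on average, may follow the hormone signal of each animal. Within the strains its deviations followed the mean of the other glucocorticoid-responsive genes (Pearson r = 0.90, exact permutation p = 0.00694, adjusted p = 0.0139 over 2 relations, Spearman rho = 0.81, exact permutation p = 0.0104, adjusted p = 0.0208). The range of Zbtb16 was 0.087 within PD5 and 1.73 within SHR, so the Pearson r of 0.90 rests mainly on the SHR animals. Without SHR 219 and SHR 215 the r was 0.42 (exact permutation p = 0.0833), so the relation rests on those animals and stays open. With that mean as a covariate the difference was 1.01 (SE 0.43) against -0.75 without it, an extrapolation, because the mean does not overlap between the strains. The test of a sequence difference under the probe sets left it open: 7 of 7 probe sets were lower in PD5, but only 1 with an interval below 0. The animals argue against such a difference as the only source of the lower average. SHR 213 and SHR 215, at 7.91 and 7.74, lay close to the PD5 mean of 7.74, and the range within SHR was 1.73. A fixed offset in PD5 added to these differences between animals cannot be excluded.

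Single animals far from the rest of their group were found in 16 of 202 groups of 4, of which about 1 in 20 is flagged by chance, or 10.1 groups. In PD5 212, Myl7 was at 9.99 with the others up to 9.19, Adora2a at 7.73 with the others up to 7.59, Ptger4 at 8.80 with the others from 8.88, and Upk3b at 5.28 with the others from 5.87. In PD5 207, Ncam1 was at 8.24 with the others up to 7.93, Rsad2 at 9.38 with the others up to 9.09, and the interferon list mean at 0.34 with the others up to -0.04. In PD5 209, Cd163 was at 7.06 with the others from 7.32, and Klf9 at 9.67 with the others from 9.79. In PD5 210, Pdk4 was at 10.66 with the others up to 10.38, and the adipocyte marker mean at 0.99 with the others up to -0.11. In SHR 213, Nr4a3 was at 6.73 with the others up to 6.16, and the fatty acid list mean at 0.08 with the others up to 0.01. In SHR 215, Ndufa2 was at 8.93 with the others up to 8.60. In SHR 219, the fibroblast marker mean was at 0.10 with the others up to -0.03, and the granulocyte and mast cell marker mean at 0.14 with the others up to -0.02.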

How the results depend on the processing

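The joint removal of PD5 210 and SHR 219 was chosen after seeing the data. The 9 genes kept their sign in every alternative in which they were tested, but not their calls. The count was 25 with the dimmest genes left out (8 of the 9 among them), 47 with a trended robust variance model (8 of the 9), 5 with median centring, 2 genes when each probe set was tested on its own, 0 with the brightest probe set per gene (908 at an unadjusted p under 0.05), 0 in the ordinary test without moderation (989) and 0 without PD5 210 and SHR 219 (914). With one array left out it was 1 without PD5 210 or SHR 218, 2 without PD5 207, 3 without SHR 219, 4 without PD5 212 or SHR 213, 5 without PD5 209 and 7 without SHR 215, and Nr4a1 passed in all 8. Lists called, 5 at first, numbered 8 with the median of the probe sets, 2 with the brightest, 0 with an estimated correlation, 1 in fry in one direction, 7 in fry in either direction, and from 2 without SHR 218 to 8 without SHR 219, with 3 without PD5 210 or SHR 213. The glucocorticoid list stayed called in all 16 alternative fits, with medians from -0.43 to -0.21 (adjusted p from 5.34e-18 to 1.32e-09), and the immediate early list likewise, with medians from 0.09 to 0.22. These fits all kept camera's preset correlation. With an estimated correlation neither list was called (camera adjusted p = 0.194 for both). In fry in one direction the immediate early list was not called (adjusted p = 0.0713). The interferon median ranged from -0.030 without PD5 207, its highest array, to 0.12 without PD5 210 and 0.14 without PD5 210 and SHR 219. Cell cycle genes, not called at first, were called in 6 of 16 alternative fits, and fatty acid genes, also not called at first, in 5 of 16. Genes whose probe sets moved apart, 61 at first, numbered 11 without the dimmest probe sets, 37 without PD5 210 and SHR 219, and from 8 without PD5 212 to 132 without SHR 218. Candidates around Zbtb16 stayed at 0 in all 16 alternatives, as did probe sets with no single gene in all 9 and genes near Zbtb16 in both other windows. Over 1186 alternative values of 75 named genes, 1080 kept their side of the threshold, 74 lost a call and 32 gained one. Only the 9 genes that passed at first could lose a call, and most of the 1080 values belong to genes that did not. Over 17 settings, the first included, Nr4a1 passed in 15, Kcna5 and Nfkbia in 12, Nr4a3 in 10 and Ch25h in 8. Ddit4 passed in 7, Timp4 in 6, Irs2 in 5, and Cryge in 3 of 16. Leaving out an array also lowers the number of samples, but the counts differed by which array was left out. The cause of these changes was not tested.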

Other observations

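The lists in the first paragraph were written after the main result but before their own values were seen, and the clock genes and the relation of the lists within strains were looked at after it. In the second list of glucocorticoid-induced genes, the steroid sulfate transporter gene Slc10a6 was at -0.75 (SE 0.18), the stress-linked gene Fam107a at -0.58 (SE 0.15), the small GTPase gene Rhob at -0.35 (SE 0.09) and Sesn1 at -0.19 (SE 0.08), while Cdkn1c was at 0.09 and Litaf at 0.11. In the list of activity-dependent genes, the kinase gene Sik1 was at 0.58 (SE 0.11), Gem at 0.34 (SE 0.07), the phosphodiesterase gene Pde4b at 0.30 (SE 0.09) and Dusp4 at 0.29 (SE 0.08), while Arc went the other way at -0.37 (SE 0.10).

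Among clock genes, Bmal1 and Nfil3 were both at 0.24, Dbp at -0.28, Tef at -0.20 and Per2 at -0.42. Hlf, which belongs with Dbp and Tef, went the other way at 0.27, Nr1d1 was at -0.05 and Per3 at -0.08, and none passed over all genes. Within the strains, the mean of the immediate early list did not follow that of the glucocorticoid-responsive genes without Zbtb16 (Pearson r = -0.19, exact permutation p = 0.729, adjusted p = 0.729, Spearman rho = 0.07, exact permutation p = 0.894, adjusted p = 0.894, and r = 0.19 without SHR 219 and SHR 215). Ucp1, a gene of brown fat, was at 9.05 in PD5 210 and between 3.79 and 4.83 in the other 7 animals.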
